A study of Mus musculus with 2 samples.

How the data were processed

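The series held 2 one-colour Affymetrix mouse expression arrays with 45101 probe sets each, hybridised with biotin-labelled cRNA from cultured endometrial stromal cells. The cells, the connective tissue cells of the uterine lining, came from female Kunming mice on day 4. The design text of the series calls this day of pregnancy and the sample labels call it pseudopregnancy, and the difference could not be settled here. Per the labels' protocols, both cultures received 10 nM estradiol-17β and 1 μM progesterone in medium with 0.5% charcoal-stripped serum for 72 h, a treatment used to induce decidualization, the change of stromal cells that prepares the uterus for an embryo. One culture also received 10 μM all-trans retinoic acid (ATRA), the vitamin A derivative that acts through nuclear retinoic acid receptors. Total RNA was extracted with Trizol, and 6 μg was labelled for each array.

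The authors deposited 1 summarised value per probe set and array on a log2 scale. The scale was read from the values, which ran from 2.13 to 14.91; natural logarithms of that size would exceed a 16-bit scanner. Affymetrix Expression Console 1.0 and Partek are named in the submitters' processing notes. The summary algorithm, the background correction, the scaling between arrays and any genome build are not given in the sources used here, and no detection calls were used. A log2 summary that shrinks dim signals would make differences of dim genes too small.

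Probe sets were named through the platform annotation, which listed 35890 probe sets: 34958 with 1 gene symbol and 932 with several. The other 9211 are unnamed here. Gene IDs of 34754 of the probe sets with 1 symbol matched the RefSeq gene table of GRCm38.p6, and 0 symbols needed updating. That table served only for names, so no coordinates are given. Leaving out 64 control probe sets, 18193 genes had a value. For genes with several probe sets, the one with the highest mean over both arrays was used.

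The comparison was the ATRA array minus the control array. With 1 array per group there is no replicate check and no p-value, and genes were counted by size alone. A gene was measured when the higher of its values reached a brightness floor, the median over all probe sets of the higher value (5.80). It was counted when its log2 difference was at least 1, which is 2-fold. No centring was applied, because the medians of the arrays differed by -0.07, less than the limit of 0.1. The repeated measurement available within these arrays was the set of probe sets of one gene. Their pooled SD of the log2 difference was 0.38 over 5078 genes with at least 2 probe sets above the floor. This SD covers technical error between probe sets, pooled over all brightness levels. It covers neither the variation between cultures nor an error shared by all probe sets of an array. The number of arrays limits the precision of every value.

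The 25 gene lists, the rule for counting and the rule for named genes were fixed before the data were examined. The rule named the 8 genes with the largest difference in each direction whose probe sets above the floor had the same sign. It also named the 3 measured members of each list with the largest absolute difference, plus Cyp26a1, Rarb, Dhrs3, Stra6, Prl8a2, Bmp2, Wnt4, Hand2, Hoxa10 and Alpl. Each list was described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on mean level in 20 bins. The percentile describes these 2 arrays, since genes are not replicates. Bounds on list medians are 95% percentile bounds from 10000 bootstrap draws of genes. Symbols in the lists that had been replaced were looked up among the synonyms of the RefSeq table. A further 5 lists were added after the differences had been seen, and they appear only in the closing section.

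The alternatives were other scalings (median centring, quantile normalization and loess with a span of 0.3), other floors (none and the 75th percentile), other rules for a gene's value (the mean of all probe sets, and the probe set with the largest difference), leaving out probe sets with the suffix s_at or x_at, and thresholds of 1.5-fold and 4-fold. The mean of all probe sets took in those below the floor. A pseudocount was not varied, because the values are already on a log2 scale. Centring on either kind of spike-in RNA was added after the control probe sets had been seen. Counting was tested on a simulated pair of arrays with an SD of 0.3 per array. It recovered 88.0% of the 50 genes raised and 88.0% of the 50 genes lowered by 1.5 on the log2 scale, 100.0% of those changed by 2.5, and counted 2.08% of 11935 unchanged genes. The simulated noise was independent between probe sets and equal at all brightness levels, without variation between cultures or a shift between arrays. These shares are therefore no error rates for the real arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.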

Results

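The data were 2 expression arrays of mouse endometrial stromal cells kept for 72 h in 10 nM estradiol and 1 μM progesterone, 1 array of a culture without ATRA (control) and 1 of a culture with 10 μM ATRA. The design asks how ATRA alters gene expression in stromal cells under conditions that induce decidualization. Median log2 signals were 5.64 on the control array and 5.57 on the ATRA array, and the arrays correlated with a Pearson r of 0.97 across probe sets, which are not independent replicates. Neither condition had a replicate, so each difference compares these cultures only. Differences below are log2 values, ATRA minus control. The SD of 0.38 between probe sets of one gene covers a part of the technical spread behind them, and no error shared by a whole array.

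The ATRA array was lower in genes of the decidual response, fibrillar collagens, contractile proteins, mitosis and cholesterol synthesis, and higher in single genes such as the matrix metalloproteinases Mmp3, Mmp10 and Mmp12, the chemokines Cxcl1 and Cxcl2 and the stress gene Atf3. It was also higher in the list of apoptosis and p53 genes, where 20 of 24 measured members had a positive difference. Of 12156 measured genes, 922 were at least 2-fold higher with ATRA and 691 at least 2-fold lower. The larger differences lay on the lower side, with 175 genes at least 4-fold lower against 116 at least 4-fold higher, and 21 at least 16-fold lower against 7 at least 16-fold higher. Of the 1613 counted genes, 57.2% were higher, a share that was 45.0% after loess, 24.5% after centring on the poly-A spike-ins and 96.2% after centring on the hybridization spike-ins. Set against the floor where the lower array lay below it, 855 of the higher and 621 of the lower genes were still at least 2-fold different. Among the 708 counted genes with a second probe set above the floor, 94.9% had the same direction in both and 54.8% were at least 2-fold in both. Among 4370 genes within 2-fold, the direction was shared in 74.8%.

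The gene with the largest difference was Prl8a2, the decidual prolactin-related protein used as a marker of mouse decidualization, at 12.18 without and 4.33 with ATRA (-7.86). It was followed on the lower side by Ecrg4 (-5.67), Tdo2 (-5.63), Col1a1 (-5.24), Vegfd (-5.18), Coch (-5.15), Hsd11b2 (-5.09) and Scgb1a1 (-5.09). Vegfd encodes a lymphangiogenic growth factor, and its 3 probe sets ranged from -5.23 to -4.50, while those of Ecrg4 ranged from -6.97 to -1.45. The ATRA levels of Prl8a2, Ecrg4, Tdo2, Vegfd and Scgb1a1 lay below the brightness floor. Set against the floor, Prl8a2 was 83.7-fold lower, Ecrg4 33.2-fold, Vegfd 31.4-fold, Scgb1a1 14.7-fold and Tdo2 7.25-fold. On the higher side stood Cxcl2 (5.65), Lyve1 (5.25), Fgf21 (4.93), Mndal (4.89), Mmp3 (4.18), Rab33a (4.10), Atf3 (4.07) and Arfgef3 (3.98). Lyve1 is a hyaluronan receptor known from lymphatic endothelium, Fgf21 a stress-induced hormone, and Mndal a member of the Ifi200 family. Control levels of Cxcl2, Lyve1, Mndal and Arfgef3 lay below the floor, against which they were 17.1-fold, 20.7-fold, 12.3-fold and 6.56-fold higher.

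**Figure D1:**
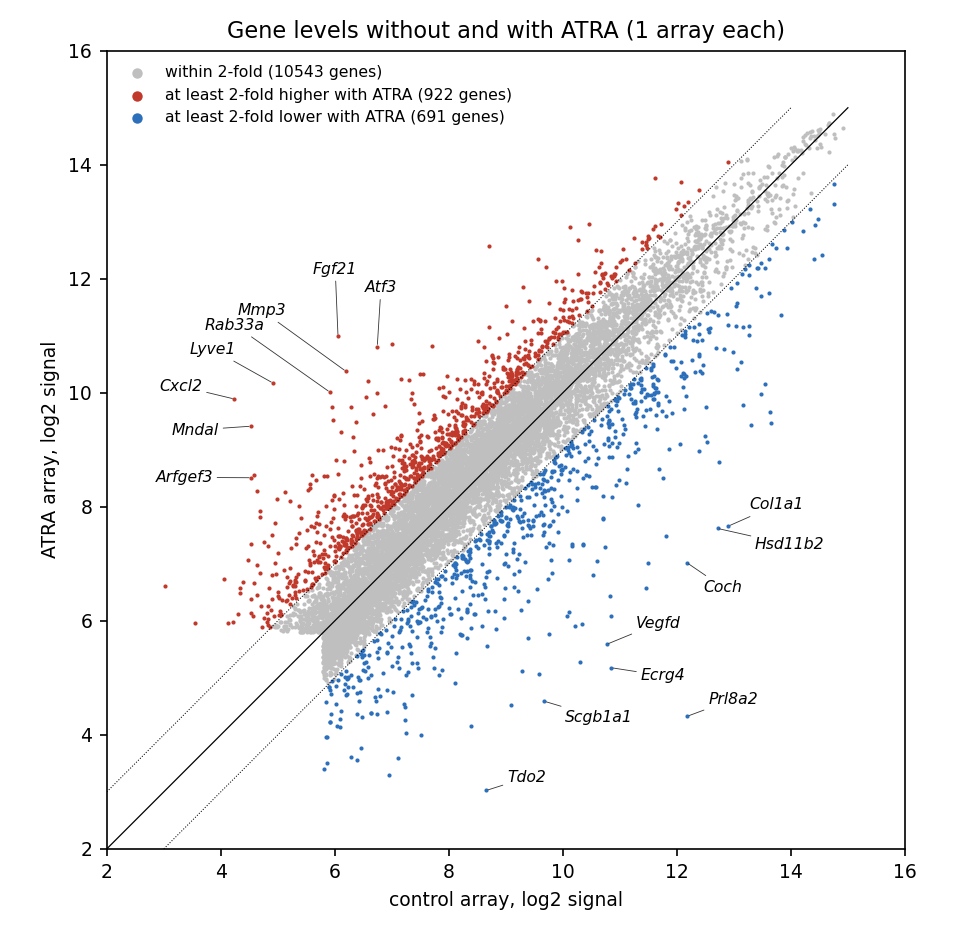
Log2 signal of each measured gene on the control array (horizontal axis) and the ATRA array (vertical axis), 1 point per gene. Red points are the 922 genes at least 2-fold higher with ATRA, blue points the 691 at least 2-fold lower, grey points the rest, the solid line marks equal levels, the dotted lines 2-fold, and the named genes have the 8 largest differences in each direction, with Prl8a2 farthest from equality.

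Genes of the decidualization list were lower with ATRA. Of 33 measured members, 13 were at least 2-fold lower, 2 higher and 18 within 2-fold. Hand2, a progesterone-regulated transcription factor, was lower by 3.02 (from 11.68 to 8.66, with a second probe set at -0.76), Hoxa10 differed by -1.49 (-0.87 as the mean of its probe sets) and Wnt4 by -1.47. Bmp2, which acts upstream of Wnt4 in decidualization, was 2.11-fold higher (1.07, but 0.92 after quantile normalization and 0.91 after loess), and Klf9 was 2.37-fold higher (1.24, with the lowest of 6 probe sets at 0.72). Alpl, alkaline phosphatase, differed by -0.62, within 2-fold. The median of the list was -0.79, below the medians of all 10000 matched random lists, and it was -0.013 when the arrays were centred on the hybridization spike-ins, which moved the median of all measured genes from 0.10 to 0.94.

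Most measured members of the retinoic acid response list stayed within 2-fold. At least 2-fold different were 28.6% of them, against 13.3% of all measured genes. Of 14 measured members of that list, 3 were at least 2-fold higher: Dleu7 (3.23), Meis2 (1.65) and Dhrs3 (1.35), a reductase that returns retinal to retinol. Rarb, the retinoic acid receptor gene that retinoic acid induces, was at 10.39 without and 11.17 with ATRA (0.78). Stra6, a retinol transporter, differed by 0.24. Cyp26a1, the main enzyme of retinoic acid breakdown, lay below the floor on both arrays (4.41 and 4.84). Rarres2 was at least 2-fold lower (-1.06, with a second probe set at -0.84). The list median of 0.24 lay at percentile 74.4 of the random lists. It was 1.06 when the arrays were centred on the hybridization spike-ins and -0.09 when centred on the poly-A spike-ins.

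Genes of retinoid supply were lower. In the list of retinoid synthesis, transport and partner receptors, 5 of 19 measured members were at least 2-fold lower and 0 higher. These were Bco1, which cleaves β-carotene (-2.98), the retinaldehyde dehydrogenases Aldh1a1 (-2.30) and Aldh1a2 (-1.55), the binding protein Crabp1 (-1.95, but -0.96 when set against the floor) and the alcohol dehydrogenase Adh1 (-1.75). The list median was -0.63, below all random lists, but 0.19 when centred on the hybridization spike-ins.

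Collagen and basement membrane genes were lower as a group, 18 of 27 measured members at least 2-fold, with a median of -1.36 below all random lists. Col1a1 was at 12.90 without and 7.66 with ATRA, Postn differed by -4.18 and Col6a2 by -3.96. Tnc was the member at least 2-fold higher (1.08). The contractile list had 11 of 14 measured members at least 2-fold lower and a median of -1.46, also below all random lists. Its largest differences were in Actg2 (-4.46), Cnn1 (-3.98) and Myh11 (-3.68, with a second probe set at -0.32), markers of smooth muscle. Both medians kept their sign under every scaling tried, with the values nearest 0 at -0.54 and -0.64 after centring on the hybridization spike-ins. The endothelial markers Eng (-1.81), Emcn (-1.65, but -0.59 when set against the floor) and Ramp2 (-1.44) were also at least 2-fold lower, Cdh5 was higher (1.24), and the 10 measured endothelial markers had a median of -0.23.

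Matrix proteases and their inhibitors went both ways: 6 of 23 measured members were at least 2-fold higher and 8 lower. The stromelysins Mmp3 (4.18) and Mmp10 (3.61) and the macrophage elastase Mmp12 (3.97) were among the largest differences on the arrays. The list median of -0.37 lay at percentile 0.03, while the mean was 0.05, and centring on the hybridization spike-ins gave a median of 0.45.

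Chemokines and cytokines were likewise split, with 3 of 20 measured members at least 2-fold higher and 5 lower. The neutrophil chemokines Cxcl2 (5.65) and Cxcl1 (3.85, with probe sets between 1.58 and 3.85) and the cytokine Lif (1.53) were higher. Cxcl14 (-3.24), Il6 (-2.36, but -0.07 when set against the floor), Cxcl12 (-1.84, with a second probe set at -0.60), Saa3 (-1.62) and Csf1 (-1.59) were lower. The list median was 0.04, at percentile 55.4. Among leukocyte markers, S100a8 (3.26), Cd68 (2.83) and Cd14 (1.39) were higher and Csf1r lower (-1.82, with probe sets up to -0.91), with 9 of 23 named markers measured and a median of -0.16. The interferon list had a median of -0.15 (percentile 12.5) and a mean of 0.03. In it Cxcl10 was higher (2.83), Irf7 lower (-1.18, but -0.39 when set against the floor), and Irgm1 differed by -0.65.

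Genes of mitosis were lower. Of 30 measured genes of mitosis and DNA replication, 18 were at least 2-fold lower, among them Rrm2, a subunit of ribonucleotide reductase (-4.33, with 3 probe sets from -4.33 to -3.62), the cyclin Ccnb2 (-2.96) and the centromeric histone Cenpa (-2.74). Many of them lay below the floor with ATRA, and set against it 10 of the 18 were still at least 2-fold lower and the list median was -0.63. The replication genes Mcm2 (1.75), Cdt1 (1.19) and Hells (1.11, with a second probe set at -0.47) were at least 2-fold higher. The list median of -1.23 lay below all random lists, but with the floor at the 75th percentile 7 members remained and the median was 0.63. Of these, Mcm2, Cdt1, Pcna (0.84) and Mcm7 (0.63) were higher and Rrm1 (-0.60), Rrm2 and Cdk1 (-1.55) lower. Most of them are genes of replication, so this median says little about mitosis. Among G1 cyclins and CDK inhibitors, 17 of 18 stayed within 2-fold. Cdk6 was the exception (-1.33, with a second probe set at -0.89), Rb1 differed by 0.84 and Rbl1 by 0.83, and the median was 0.39 (percentile 92.1), or 0.06 and 1.21 when centred on the poly-A and the hybridization spike-ins.

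Stress genes were divided. In the endoplasmic reticulum stress list, 7 of 27 measured members were at least 2-fold higher and 2 lower. The higher genes were Atf3 (4.07), Trib3 (1.82) and Ppp1r15a (1.62), which act in the ATF4 branch, and Ern1, Atf6, Atf4 and Ddit3. Ern1 differed by 1.56 (with a second probe set at 0.22), Atf6 by 1.33, Atf4 by 1.14 and Ddit3 by 1.13 (with a second probe set at 0.28). The lower genes were the folding factors Creld2 (-1.41) and Pdia4 (-1.13). The list median was 0.20, at percentile 75.8. In the apoptosis and p53 list, 6 of 24 measured members were at least 2-fold higher and 0 lower, with a median of 0.55 at percentile 99.7, which was 0.22 when centred on the poly-A spike-ins and 1.37 when centred on the hybridization spike-ins. The largest were the growth arrest gene Gadd45a (2.40), the BH3 protein Bid (1.70, with a second probe set at 0.05) and Trp53inp1 (1.40, but 0.56 as the mean of its probe sets).

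Cholesterol synthesis genes were lower almost throughout: 19 of 20 measured members had a negative difference and 9 were at least 2-fold lower. Nsdhl (-2.17), Tm7sf2 (-1.82) and Pmvk (-1.31) led the list, whose median of -0.88 lay below all random lists and was -0.06 after centring on the hybridization spike-ins. In the lipid and PPAR list, Angptl4, an inhibitor of lipoprotein lipase, differed by -4.40, in an s_at probe set. Without such probe sets its difference was -0.58, from a probe set below the floor. Cd36 differed by -2.17 (-0.68 when set against the floor) and Scd1 by -1.51, and Plin2 was higher (1.15). The list median was -0.29 (percentile 0.68), with 6 of 20 members at least 2-fold lower, and 0.53 when centred on the hybridization spike-ins.

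Among genes of steroid action, the enzymes that convert glucocorticoids, Hsd11b2 (-5.09) and Hsd11b1 (-3.29), were lower, as were Fkbp5 (-2.39, with a second probe set at -0.91) and the estrogen receptor Esr1 (-1.96), while the hedgehog receptor Ptch1 was higher (1.33, with a second probe set at -0.15). The list median of -0.07 lay at percentile 8.74, with a mean of -0.69. In the Wnt list, 7 of 24 measured members were at least 2-fold lower, led by the antagonists Sfrp4 (-4.88) and Dkk2 (-3.45), and the agonist Rspo1 was higher (2.64); the median was -0.45 (percentile 0.01), and 0.37 when centred on the hybridization spike-ins. In the BMP and TGF-beta list, 10 of 28 were at least 2-fold lower, with Bmp4 (-3.94), Bmp1 (-2.52) and Tgfb3 (-2.47) first, and Tgfbi (2.06, with probe sets from 0.85 to 3.25) and Inhba (1.23) were higher; the median was -0.30 (percentile 0.13), -0.14 when set against the floor, and 0.74 with that centring. In the prostaglandin list the receptors Ptgir (2.20) and Ptger4 (1.41) and the synthase Ptges (1.05) were higher and Ptgds (-1.09) and Slco2a1 (-1.03) lower (as the mean of the probe sets, Ptger4 was at 0.92 and Ptgds at -0.84), with a median of -0.24 (percentile 5.95) and a mean of 0.10. Of 14 measured genes in the Hox list, 0 were 2-fold different. That list leaves out Hoxa10 and Hoxa11, which are in the decidualization list and were at least 2-fold lower. They differed by -1.49 (-0.87 as the mean of its probe sets) and -1.18. Hoxd11 (-0.96), Hoxb2 (0.64) and Hoxd10 (-0.63) differed most, and the median was -0.11 (percentile 15.5).

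**Figure D2:**
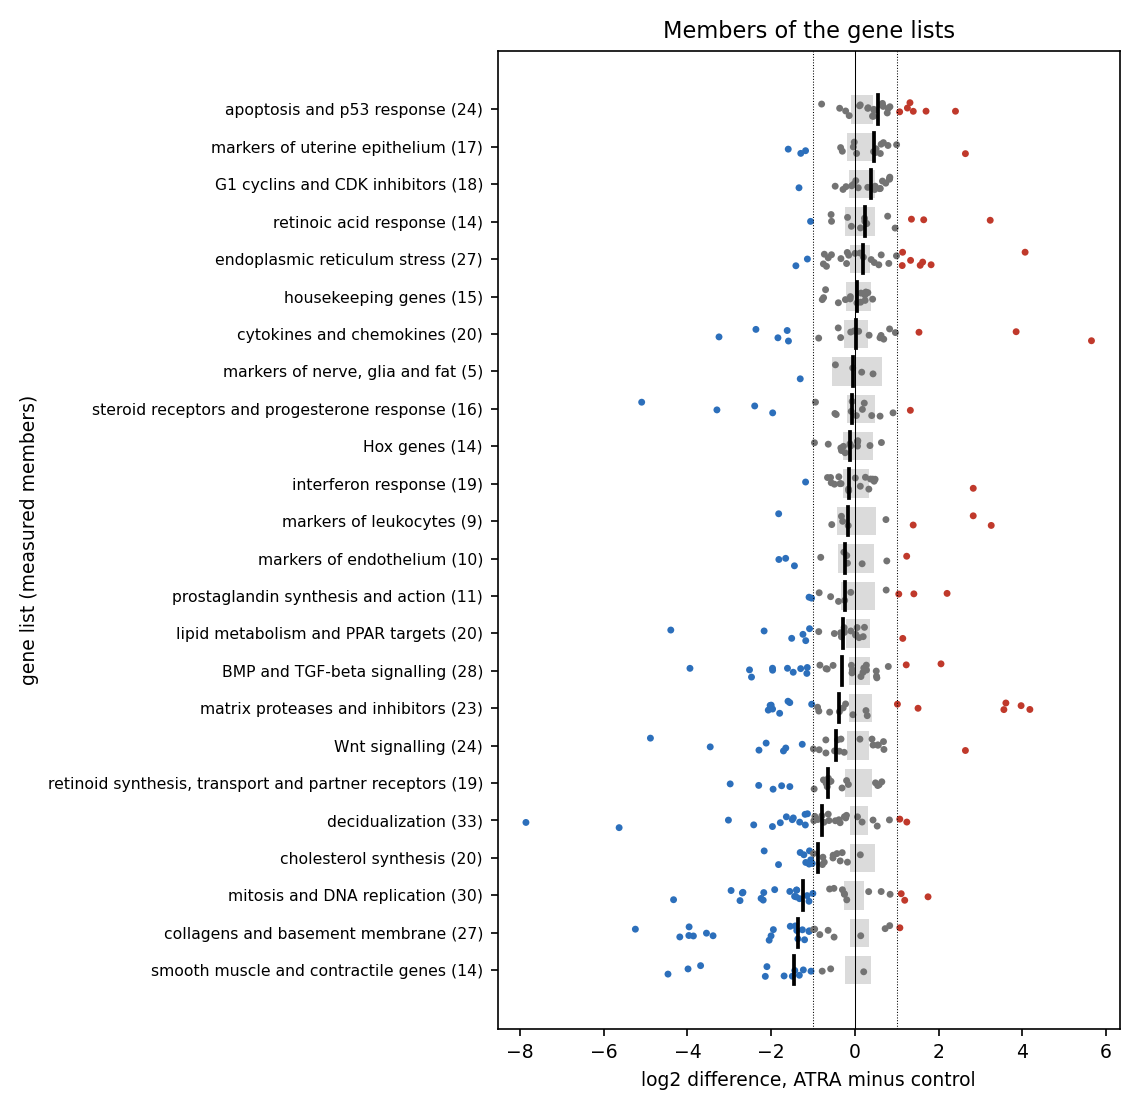
Log2 difference (ATRA minus control, horizontal axis) of each measured member of the gene lists with at least 5 measured members, 1 row per list and 1 point per gene, with the number of measured members in brackets. Red and blue points are at least 2-fold higher and lower, the black bar is the list median, and the grey band holds the medians of 95% of 10000 matched random lists; the contractile, collagen and mitosis medians (-1.46, -1.36 and -1.23) lie farthest below their bands.

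Epithelial markers differed in both directions, 10 of 17 measured markers with a positive difference and 7 with a negative one. At least 2-fold different were Prom1, which was higher (2.64), and Krt7 (-1.59), Ltf (-1.29) and Epcam (-1.18, with a second probe set at 0.20), which were lower. The list had a median of 0.45 (percentile 96.0, mean 0.18). That median was 0.01 without a floor, 0.12 when centred on the poly-A spike-ins and 1.27 when centred on the hybridization spike-ins. Of the red blood cell markers, Car2 alone was measured (-0.06). In the list for nerve, glia and fat, Ngfr was lower (-1.30, but -0.51 as the mean of its probe sets), S100b differed by 0.43 and Sox10 by -0.46 (probe sets from -0.69 to 0.26), and the median of 5 was -0.05 (percentile 51.6). Of 15 measured housekeeping genes, 0 were 2-fold different. Gusb (-0.78), Vcp (-0.75) and Pgk1 (-0.70) differed most, and the median was 0.05 (percentile 33.8, mean -0.08).

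The remaining genes named above that lay below the floor on 1 array are given here against the floor, since the size of a difference is least certain there. Set against the floor, the differences were 2.76 for Mmp12, 2.13 for Dleu7, 1.93 for Tgfbi, 1.55 for Cxcl10, 1.34 for Ptger4 and 0.15 for S100b on the higher side. On the lower side they were -3.96 for Cnn1, -3.59 for Myh11 and -1.43 for Ccnb2 and for Cenpa.

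The control probe sets differed between the arrays. The 18 probe sets for hybridization spike-ins, bacterial and phage transcripts added to the hybridization mix, were lower on the ATRA array by a median of -0.82 (range -1.05 to -0.30). The 24 probe sets for the poly-A spike-ins had a median difference of 0.33 (range -0.02 to 0.53), and the 3 for 18S ribosomal RNA one of -0.82. Centring on the hybridization spike-ins made the medians positive for the steroid (0.75), interferon (0.89), Hox (0.72), prostaglandin (0.65), endothelial (0.64), leukocyte (0.66) and nerve, glia and fat (0.77) lists and the value of Car2 (0.76). Centring on the poly-A spike-ins made them negative for the endoplasmic reticulum stress (-0.12), cytokine (-0.29) and housekeeping (-0.28) lists. The log2 ratio of 3' over 5' signal, a sign of RNA integrity, was 0.25 on the control array and 0.41 on the ATRA array for Gapdh, and 0.77 and 1.00 for Actb.

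The rule fixed before the data were examined did not cover Klf9, Rarres2, Adh1, Aldh1a2, Tnc, Cdh5, Lif, Il6, Cxcl12, Saa3, Csf1, Cd14, Mcm2, Cdt1, Hells, Creld2, Pdia4, Plin2, Esr1, Ptch1, Tgfbi, Inhba, Ptges, Slco2a1 and Epcam. These genes complete counts of 5 or fewer. The rule also did not cover Ern1, Atf6, Atf4 and Ddit3, which complete a count of 7, or Timp1, Htra3 and Mmp19, the lowest of their list. Nor did it cover Hoxa11, which the Hox list leaves out, or Mcm7, Pcna, Rrm1 and Cdk1, which remain at the higher floor. All were chosen after their values were seen.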

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

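The tests of exchanged labels, of scaling, of other cell types and of single cultures, and the test of decidual against stromal identity genes, were chosen after the values they bear on had been seen, and those of scaling and of other cell types were run in more than one form.

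Probe sets that the annotation gave to no gene or to several genes stood outside the comparison. Above the floor, 98 of these 2285 probe sets were at least 2-fold higher with ATRA and 97 at least 2-fold lower. They were picked out as signal in data left out of the gene comparison. The largest difference, 6.29 (5.28 without and 11.57 with ATRA), exceeds that of every named gene on the higher side. The annotation gives this probe set several genes, so it carries no name here.

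Collagen, contractile and decidual genes were lower relative to other genes, with list medians of -1.36, -1.46 and -0.79. Scaling between the arrays is argued against as the whole cause of this order, since the highest of the medians minus that of all measured genes was -0.81 under quantile normalization and loess (first form: -0.72 for the medians themselves, median centring included), but a shift of all genes is not, and centring on the hybridization spike-ins put the decidual median itself at -0.013. Epithelial or endothelial cells in place of stromal cells are argued against as the whole cause. All named markers were taken, below the floor or not. The upper 95% bootstrap bounds of their median minus that of all genes were at most 0.56 and 0.14. Both lay below the 1 set for this test after the values had been seen. Lyve1 (5.25), known from lymphatic endothelium, was not among the endothelial markers. For leukocytes the upper bound was 0.18, but 14 of the 23 markers lay below the floor on both arrays, so leukocytes stay open. These bounds are the highest over the scalings, but median and spike-in centring shift every gene alike and cannot change them. The leukocyte test was tried in 3 forms. Over measured markers alone the bounds were 0.55, 0.74 and 2.75 for epithelial, endothelial and leukocyte markers, which decided nothing for leukocytes. In the first form 8 of 23 leukocyte markers reached the floor on the ATRA array. S100a8, Cd68 and Cd14 were higher and Csf1r lower (-1.82), while Ptprc, Adgre1, Tyrobp, Itgam and S100a9 lay below the floor on both arrays. A larger share of some leukocytes stays open. The 18 measured stromal identity genes, a list written after the differences had been seen, were themselves lower, with a median of -0.50 (percentile 0.09). Of them, 6 were at least 2-fold lower and 1 higher, so a partial general loss of stromal transcripts stays open. The collagen and contractile medians lay below that of the stromal identity genes by at least 0.23 (lower bound), and for decidual genes that bound was -0.34. Because the stromal identity genes were chosen with the differences known, these bounds cannot decide whether such a loss is the whole cause. For all these lists the matter stays open. An effect of ATRA and a difference between single cultures cannot be told apart with 1 array per group.

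The median of retinoic acid targets was little higher with ATRA (0.24). Exchanged array labels stay open: the mean difference of Rarb, Dhrs3, Cyp26a1 (below the floor), Cyp26b1 and Stra6 was 0.62, but its 2 standard errors of 0.34 cover probe sets and not cultures. That mean was 0.29 after centring on the poly-A spike-ins and 1.44 after centring on the hybridization spike-ins. Of the 14 measured members of the whole list, 9 were positive and 5 negative. Signal near saturation is argued against because the brightest of these genes lay 2.83 below the brightest probe set. Whether these targets were already active in the control culture was not tested.

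Hybridization spike-ins were lower on the ATRA array by a median of -0.82. Brightness-dependent scaling between the arrays does not account for this, since the median offset after loess was -1.01 (SD 0.28 over 18 probe sets). No biological explanation was tested. Unequal amounts of labelled cRNA or of spike-ins stay open, and because the poly-A spike-ins differ in the opposite direction, these arrays do not fix an absolute level.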

How the results depend on the processing

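With 1 array per group no array could be left out. No paired analysis was possible because each group has 1 array. The counts of genes higher and lower with ATRA, 922 and 691, ranged from 579 (mean of all probe sets) to 1233 and from 512 (floor at the 75th percentile, which admits fewer genes) to 845 under the scalings, floors and probe set rules set before the data were seen. A threshold of 1.5-fold gave 2498 and 1513, and one of 4-fold 116 and 175. After loess, 671 of the 922 and 676 of the 691 were still counted. Without a floor, the share of second probe sets with the same direction dropped to 88.2%. Centring on the hybridization spike-ins, chosen after seeing the data, gave 5491 higher and 215 lower genes, and centring on the poly-A spike-ins gave 407 and 1252; both shift every gene by a constant. The first of these brought the retinoic acid response median to 1.06 and the decidualization median to -0.013. It turned the medians for retinoid synthesis (0.19), matrix proteases (0.45), Wnt (0.37), BMP and TGF-beta (0.74) and lipid genes (0.53) positive, as well as 7 further list medians and the value of Car2, all within the range of random lists or without one and given with the control probe sets, while the median of all measured genes became 0.94. The median of the list of mitosis and DNA replication was 0.63 with the floor at the 75th percentile. It left 7 of 30 members, most of them genes of replication. That floor also gave 2.11 for leukocyte markers, -1.13 for endothelial markers, -1.12 for Wnt genes, 0.33 for prostaglandin genes and -0.40 for cytokines. Where the construction of an alternative does not show the cause, the cause was not tested. Under median centring, quantile normalization and loess all 89 named genes moved by less than the SD between probe sets of one gene. Even so, Bmp2 went under 2-fold after quantile normalization and loess. The mean of all probe sets moved 21 of them by more, and Hoxa10, Cdk6, Bid, Trp53inp1, Ptger4, Ptgds and Ngfr went under 2-fold. Of these, Hoxa10, Trp53inp1, Ptger4, Ptgds and Ngfr each had 1 probe set above the floor. Their means therefore include probe sets below it. Dim genes are the limit of these arrays: 6037 genes lay below the floor on both, and apart from Cyp26a1 and the cell type markers of the tests above their differences are not read.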

Other observations

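The 4 lists tested here were written after the differences had been seen, without the genes that prompted them, and their medians had not been computed before. Genes in these paragraphs were chosen after their values were seen.

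Genes of amino acid supply that ATF4 controls were higher with ATRA. Of 23 measured members, 6 were at least 2-fold higher and 0 lower, among them the cystine transporter gene Slc7a11 (1.71), the alanine aminotransferase Gpt2 (1.52), the arginine transporter Slc7a1 (1.32) and Phgdh of serine synthesis (1.22). Of the genes named, Gpt2 had probe sets as low as 0.30 and Phgdh as low as 0.19. Vldlr (-0.23), Slc7a5 (-0.28) and Atf5 (-0.55) had negative differences. Lysosomal genes were also higher, with 5 of 27 at least 2-fold, including Fnip1 (1.83), the cholesterol transporter Npc1 (1.36), the proton pump subunit Atp6v1c1 (1.33) and the autophagy receptor Sqstm1 (1.31), against 3 lower: Mitf (-1.63), Neu1 (-1.51) and Wipi1 (-1.02). Other probe sets were nearer 0 for Atp6v1c1 (0.85), Mitf (-0.90) and Wipi1 (-0.28). Centring on the poly-A spike-ins left 2 ATF4 targets and 2 lysosomal genes at least 2-fold higher and list medians of 0.33 and 0.13, which relative to all measured genes were 0.57 and 0.37 (0.56 and 0.36 uncentred).

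The hypotheses were that single genes seen to be higher belong to wider programmes. Not all of these were strong, since Ctsk differed by 1.02. For Fgf21, Atf3 and Trib3, the ATF4 list median of 0.65 lay at percentile 99.99 of the matched random lists. For Cd68, Ctsk, Rragd and Mreg, the lysosomal list median of 0.45 lay at percentile 99.5. Both lists were higher in this ATRA culture. Because their genes were chosen with the differences known, these percentiles cannot test whether wider programmes were higher. For Mmp3, Mmp10, Mmp13, Cxcl1 and Cxcl2, the list of ERK and AP-1 targets had a median of 0.44 at percentile 96.2, short of the bound set beforehand, and Fos itself was lower (-1.88). NRF2 targets as a general stress response had a median of 0.15 at percentile 59.1, although Txnrd1 (1.82), Gsta3 (1.47, but 0.87 against the floor) and Gclc (1.08, with a second probe set at 0.48) were higher.

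Genes of the Ifi200 family of interferon-inducible genes were mixed, and the family was neither a fixed list nor tested. Mndal (4.89, or 3.62 against the floor) and Ifi204 (3.47) were higher with ATRA, as were Ifi207 (3.60, but 0.82 against the floor) and Ifi202b (9.70 without and 12.20 with ATRA), Ifi203 differed by 0.06, and Ifi209, Ifi213 and Aim2 lay below the floor on both arrays. These genes are close paralogs, and probe sets of one can bind transcripts of another.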
